A study of Homo sapiens with 5 samples.

How the data were processed

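H3K9me3 ChIP-seq was done in HEK293T cells. Per the labels' protocols, cells were crosslinked with formaldehyde, chromatin was sonicated, and the antibody was raised against H3K9me3. The labels list 5 samples, 3 H3K9me3 libraries (WT, EV and KD) and 2 input libraries (WT and EV), with 1 library per group. The deposited files are 3 lists of broad peaks without headers. The names of 2 lists carry EV and KD and were matched to those samples. The remaining list carries no genotype in its name or in its peak names. It was not assigned to WT, no WT comparison was made, and its values appear only in the closing observations.

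Reads were aligned with Bowtie2 and peaks were called with MACS2 on build GRCh38, per the submitters' processing notes, which give no versions. The calling options, the control library used for each list, the filters, and whether samples were pooled are not given in the sources used here. The fold enrichment of each peak is a ratio over the caller's background, computed by the authors with their peak caller. The deposited −log10 p and −log10 q of each peak are the authors' as well. The lists hold no −log10 q below 1.00, so they stop at about q = 0.1. These values describe, rank or filter peaks of their own list, since ranks from lists of different length show no change. Where folds of both lists are printed for one place, each is its own list's value and no difference is read from them. The planned cuts on fold enrichment were applied to both lists alike although their scaling is not known, so KD/EV values under those cuts depend on it. A comparison of the folds of paired peaks across the lists was dropped for this reason. The lists hold no read counts and the depth is unknown. A less deeply sequenced library yields fewer peaks at the same threshold, so peak number and covered length depend on depth as well as on the mark.

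Coordinates are printed counting from 1, on GRCh38. Peaks on chromosomes 1 to 22, X and Y entered the comparisons, and peaks on other sequences were set aside. Gene positions came from a RefSeq gene table of GRCh38.p14, with 58957 genes on these chromosomes, 19862 of them protein-coding. The table has neither strand nor exons, and no genome sequence was used here. Shares of repeats and GC, exon and intron context, and a promoter setting, all planned, were therefore not run. Chromosome length was taken as the last gene or peak end, since no lengths were given. Gene list members were matched on current symbols, with 4 matched through older ones.

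Overlap, at a minimum of 1 bp, and covered bases were computed with interval functions built on numpy. These gave the same counts as bedtools 2.31.1 on simulated data. Reciprocal overlaps came from bedtools. Shares have exact Clopper-Pearson 95% intervals (scipy 1.17.1), and the ratio of peak numbers has the interval of the corresponding binomial share. Random expectations came from 100 seeded placements of the peaks within their chromosomes. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9. The overlap step was tested on simulated data made from the 24665 EV peaks. It found 100% of 10000 peaks placed to overlap and called 0 of 500 distant ones.

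A gene list member was counted when peaks covered at least 10% of its gene body. Member counts were set beside 10000 random lists of the same size matched on gene length deciles, as a description of these libraries and not a test. The covered share of a list is the covered length over the summed gene bodies, where overlapping bodies were merged and counted once. The comparisons, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined, apart from those named next. Gene-free stretches of at least 2 Mb, the expected recovery of EV peaks at like strength, and a list of developmental transcription factor genes were added after the data were seen. The plan described shared and one-list peaks by fold enrichment and width. Their −log10 p, and the shares of peaks found by bin of −log10 p, were not in the plan. The expected recovery of a group is the mean share of all EV peaks found in KD in the same bin of −log10 p (20 bins) and width (3 bins).

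Named genes are protein-coding, on chromosomes 1 to 22 and X, with a gene body of at least 5 kb. They are the 10 with the largest covered share in EV minus KD, the 10 with the largest in KD minus EV, and the 10 with the largest smaller-of-both share. To these were added the KCNQ1 domain members with a peak, up to 4 members of each other list with the largest absolute difference, and per list the 3 widest peaks and the 3 with the highest fold enrichment. The text gives a selection of them. Alternatives were stricter −log10 q and fold enrichment, merging of peaks within 3 kb, other sets of sequences, equal peak numbers, and stricter overlap.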

Results

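The study profiled trimethylation of histone H3 lysine 9 (H3K9me3), a mark of silenced chromatin, by chromatin immunoprecipitation and sequencing (ChIP-seq) in HEK293T, a human embryonic kidney cell line. The labels describe 5 samples: H3K9me3 libraries from cells labelled WT, EV and KD, and input libraries from WT and EV. EV is read here as the empty-vector control and KD as the KCNQ1OT1 knockdown of the study design. The design writes the target with the suffix K, as KCNQ1OT1_K, and what the suffix stands for is not given, so the exact target of the KD group is uncertain. KCNQ1OT1 is a long non-coding RNA transcribed antisense to KCNQ1 from the imprinted domain on chromosome 11. Each group had 1 library, so the differences below have no replicate check and no test between conditions was made. Exact Clopper-Pearson 95% intervals are given for shares, and they cover counting error over peaks only. The number of reads behind each list is not given in the sources used here, so the depth is unknown. The EV and KD peak lists could be matched to their samples by name, and the comparison of KD with EV is the one reported. RNA levels were not measured in these files, so the loss of KCNQ1OT1 itself was not checked.

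At the KCNQ1 domain, the locus of the targeted RNA, the KD list held a peak at the 5′ end of KCNQ1OT1 that the EV list lacked. This peak lay at chromosome 11, positions 2698828 to 2700605 (GRCh38), within the body of KCNQ1, the gene of a cardiac potassium channel. It was 1778 bp wide, with a fold enrichment of 5.17 and a −log10 p of 11.2. KCNQ1OT1 ends at position 2699994 in the annotation, which is its 5′ end because it runs antisense to KCNQ1. Of the peak, 1167 bp lay inside KCNQ1OT1 and 611 bp beyond it. The nearest EV peak was 59.3 kb away. Of the 1296 KD peaks at least this strong, 1290 (99.5%, interval 99.0 to 99.8) were overlapped by an EV peak, and this was 1 of the 6 that were not. The knockdown method is not given in the sources used here. Some methods recruit a repressor that itself places H3K9me3 at the targeted promoter, so what this peak reflects cannot be read from these lists.

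Between TSPAN32 and OSBPL5, positions 2302013 to 3165310, the EV list held 3 peaks and the KD list 4. Both lists had a peak in CD81-AS1, a non-coding gene next to CD81. It spanned 2353058 to 2354450 with a fold enrichment of 4.13 in EV, and 2353417 to 2354117 with 3.23 in KD. Both had a further peak between PHLDA2 and NAP1L4, at 2937965 to 2938786 in EV and 2937972 to 2938807 in KD. Inside KCNQ1 and KCNQ1OT1, the EV peak at 2639061 to 2639569 and the KD peak at 2639581 to 2640150 lay side by side without overlapping. Peaks covered 0.555% of KCNQ1OT1 in EV and 1.89% in KD. CDKN1C, a cell cycle inhibitor, and PHLDA2, a placental growth gene, are imprinted genes of this domain, and neither carried a peak in EV or KD.

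**Figure D1:**
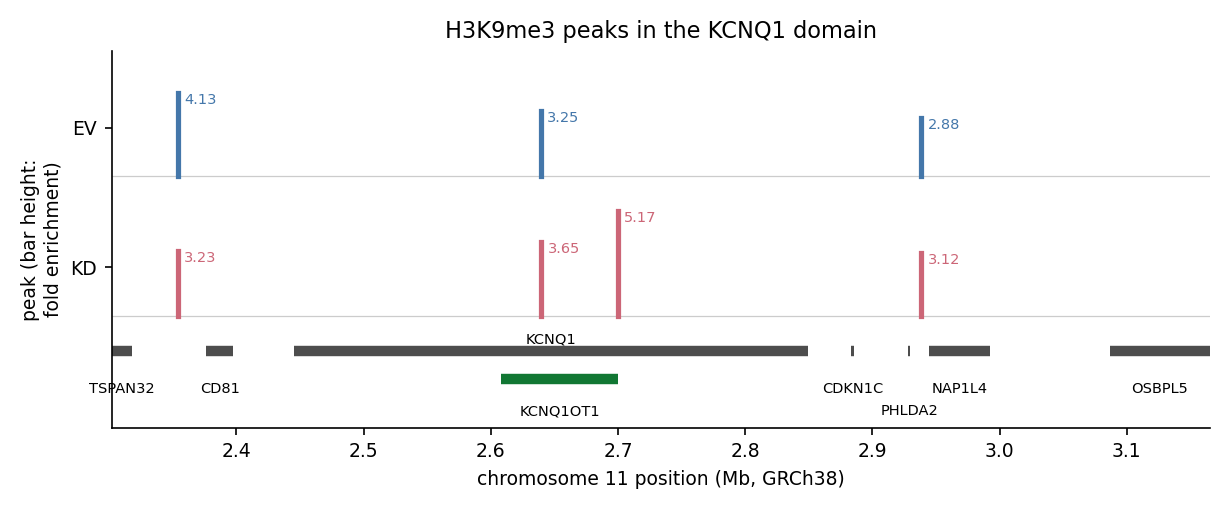
Map of the KCNQ1 domain on chromosome 11 (position in Mb, GRCh38), with EV and KD peaks drawn as bars at their midpoints, each bar's height and number giving its fold enrichment in its own list, and selected genes below. The KD bar with a fold enrichment of 5.17 stands at the 5′ end of KCNQ1OT1, where EV has none.

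Across chromosomes 1 to 22, X and Y, the KD list held fewer and less extensive peaks than the EV list. EV had 24665 peaks over 50.5 Mb and KD 12650 peaks over 20.6 Mb. The KD/EV ratio was 0.513 for peak number (interval 0.502 to 0.524) and 0.408 for covered length. Gene-free stretches of at least 2 Mb, which hold the centromeres of most chromosomes, contained 28.5 Mb of the EV coverage and 13.8 Mb of the KD coverage. These stretches held 56.5% of the covered length in EV and 66.8% in KD. There the KD/EV ratio of covered length was 0.482, against 0.311 in the remaining sequence. EV peaks in these stretches were also stronger, with a median −log10 p of 6.05 against 4.37 elsewhere. Of them, 64.9% were overlapped by KD, against 58.6% expected at like strength and width. Elsewhere these shares were 28.5% and 30.6%, so much of the contrast in overlap went with peak strength and width. Reads from repetitive centromeric sequence can match many places, and the filters are not given, so values in these stretches are uncertain. Peak number follows the caller's threshold, and limiting EV to its strongest 12650 peaks left a KD/EV covered length of 0.560.

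The widest EV peak covered 210153 bp of chromosome 1, from 122238076 to 122448228, and the widest KD peak, at 122272302 to 122370259, lay inside it. The next widest EV peaks, of 100427 and 97654 bp, both lay on chromosome 16, where 9 and 14 KD peaks overlapped them. These peaks on chromosomes 1 and 16 lay in gene-free stretches, so the same uncertainty holds for them. In KD the next widest lay on chromosome 4, with 59507 bp, and on chromosome 10, with 58034 bp, and each was overlapped by a single EV peak. The one on chromosome 10 also lay in a gene-free stretch, with the same uncertainty. The highest fold enrichment in EV, 20.4, was on chromosome 21 at 10269953 to 10272439, and the KD list had a peak of 13.2 at the same place. Peaks in LDB2, on chromosome 4, and WDR49, on chromosome 3, were also among the highest, with 15.3 in EV for LDB2 and 13.3 in KD for WDR49. Every one of these peaks was overlapped by the other list.

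Chromosome 19, which carries many clusters of zinc finger genes, had the highest covered share in EV, 5.21%, and 1.81% in KD. Much of this lay outside those genes: its gene-free stretch held 49.3% of its EV covered length, and 738132 of 1059749 bp in KD. Chromosome 22 came next in EV with 4.72%, and in KD chromosome 21 was higher than chromosome 19, with 1.85%. On the X chromosome the shares were 0.968% and 0.396%. All 23 chromosomes from 1 to 22 and X had less covered length in KD. The KD/EV ratio ran from 0.276 on chromosome 17 to 0.590 on chromosome 16, with a median of 0.427. It was 0.347 on chromosome 19 and 0.409 on X, and with equal peak numbers 0.518 and 0.720.

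**Figure D2:**
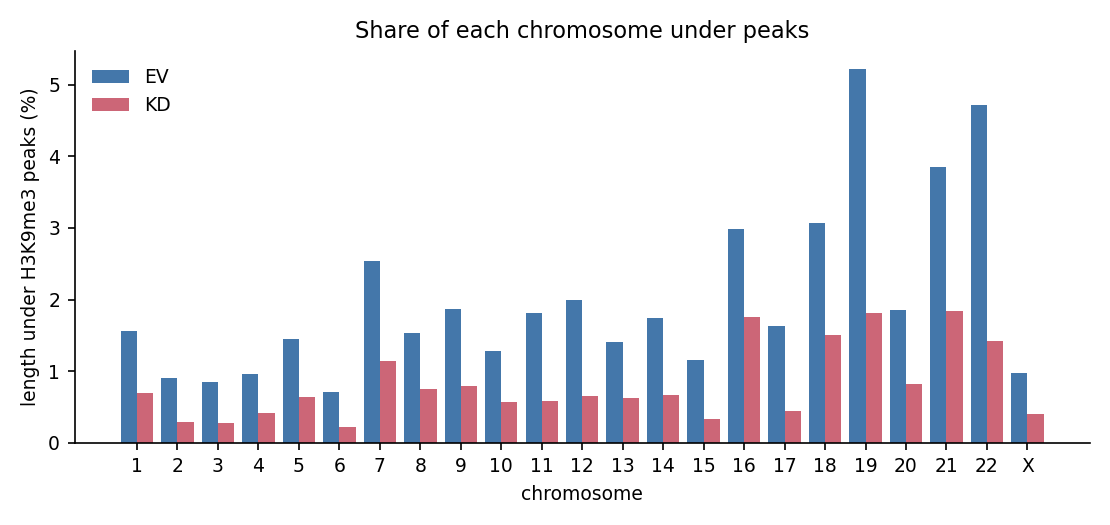
Share of each chromosome's length under H3K9me3 peaks (%), for the EV and KD lists, 1 library each. KD is lower on all 23 chromosomes shown, and chromosome 19 has the highest EV share, 5.21%.

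Most KD peaks lay where EV also had one, while most EV peaks had no KD partner. Of the 12650 KD peaks, 11093 (87.7%, interval 87.1 to 88.3) were overlapped by EV by at least 1 bp. Of the 24665 EV peaks, 9307 (37.7%, interval 37.1 to 38.3) were overlapped by KD. With peaks placed at random within their chromosomes, the shares were 3.43% ± 0.143 and 1.62% ± 0.083 (SD over 100 placements). Shared bases made up 35.5% of the union. With EV limited to its strongest 12650 peaks, most peaks had a partner both ways: 62.1% of EV and 75.9% of KD peaks.

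The EV peaks without a KD partner were the weaker and narrower ones of their list. Their median −log10 p was 3.96 and their median width 867 bp, against 7.77 and 1739 bp for shared EV peaks. Their median fold enrichment was 2.99, against 3.62 for shared EV peaks. The share of EV peaks found in KD rose from 5.32% at a −log10 p below 3.5 to 99.8% between 30 and 50 and 100% above that. The 1557 KD-only peaks had a median −log10 p of 4.26 and a median width of 500 bp. For shared KD peaks these were 5.14 and 1135 bp. Median fold enrichment differed little, with 3.58 for KD-only and 3.70 for shared KD peaks. Protein-coding genes held 36.3% of EV-only and 37.8% of KD-only peaks by midpoint, and 23.1% of shared EV peaks. These genes span 40.9% of the chromosomes' length, so none of the 3 shares exceeded it. Gene-free stretches held 43.7% of the shared EV peaks, 14.3% of the EV-only peaks and 10.7% of the KD-only peaks. With reciprocal overlap of at least 50%, the shares were 44.3% of KD and 22.7% of EV peaks.

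**Figure D3:**
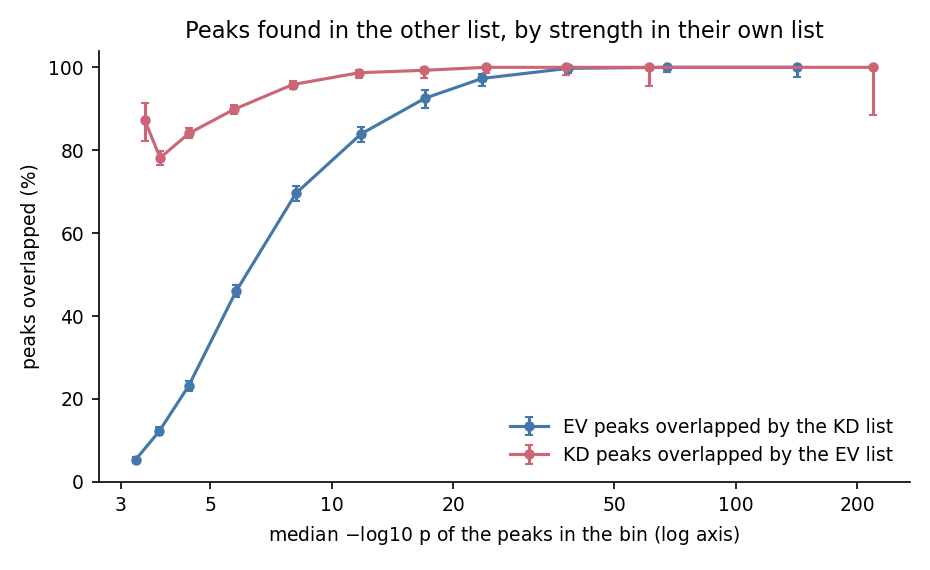
Share of EV peaks overlapped by the KD list and of KD peaks overlapped by the EV list (%), by bin of the peak's own −log10 p (log axis, bin medians), with exact 95% intervals. EV peaks are found in KD at 5.32% in the weakest bin and at 100% in the strongest.

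Among all 19862 protein-coding genes, 548 had peaks over at least 10% of the gene body in EV and 307 in KD, a KD/EV ratio of 0.560. With any overlap the counts were 4890 and 2290, a ratio of 0.468.

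Zinc finger genes had a far smaller covered share in KD than in EV. Of 240 ZNF genes on chromosome 19, which encode mostly KRAB-type repressors of transposable elements, 58 had peaks over at least 10% of the gene body in EV and 5 in KD. Their summed gene bodies were covered to 6.88% in EV and 0.929% in KD. For these genes the KD/EV ratio of covered length was 0.135, against 0.311 for all sequence outside gene-free stretches. In EV their member count exceeded that of all 10000 random lists matched on gene length, and in KD it stood at percentile 98.1. ZNF724 went from 40.5% to 4.64%, ZNF274 from 40.9% to 7.44%, and ZNF878 and ZNF317 from 37.2% and 31.1% to no peak. ZNF274 encodes a zinc finger protein that recruits the H3K9 methyltransferase SETDB1. Of the 237 ZNF genes on other chromosomes, 23 met the criterion in EV and 4 in KD, among them ZNF268 (41.1% and 1.70%), ZNF605 (48.5% and 10.1%), ZNF678 (44.5% and 11.1%) and ZNF721 (41.2% and 8.47%). The KD/EV ratio of covered length was 0.219 for the ZNF genes on other chromosomes. With EV limited to as many peaks as KD, 16 chromosome 19 members met the criterion in EV and 5 in KD. On the other chromosomes these counts were 10 and 4. No member reached 50% of the gene body in either list. With any overlap the KD/EV ratio of members was 0.405 on chromosome 19 and 0.460 on the others, near that of all protein-coding genes.

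Clustered protocadherin genes, which encode neuronal cell adhesion proteins, carried the highest covered share of any list in both EV and KD. Of 53 members, 30 met the criterion in EV and 11 in KD, each above all 10000 random lists, and the covered share was 11.8% and 6.44%. Members of this cluster overlap and share peaks, so they are not independent. PCDHGB3 had 16.7% and 4.57%, PCDHGB2 16.9% and 5.12%, PCDHB5 24.3% and 12.3%, and PCDHB14 14.3% in EV with no KD peak. Of the 49 EV peaks in these genes, 38 (77.6%, interval 63.4 to 88.2) were found in KD. The difference in members depended on the setting: with a fold enrichment of at least 3 the counts were 5 in EV and 9 in KD, and with equal peak numbers 9 and 11.

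HOX genes, regulators of body axis patterning, had 5 of 39 members with peaks over at least 10% of the gene body in each list, and 5 in EV and 6 in KD with any overlap. The counts were 2 and 4 at a fold enrichment of at least 3, and 3 and 5 with equal peak numbers. Their covered share was 2.14% in EV and 1.93% in KD. HOXD10 had no EV peak in its gene body and 29.6% in KD, but its KD peak was overlapped by an EV peak outside the gene. HOXD1 went from 32.4% to 22.3%, HOXD9 from 16.9% to 10.3% and HOXD11 from 21.7% to 16.3%. Imprinted genes outside the KCNQ1 domain met the criterion 5 times in EV and once in KD, out of 38, and with any overlap 20 had a peak in EV and 16 in KD. NNAT, which encodes the proteolipid neuronatin, had 63.7% and 12.6%, H19, a non-coding RNA, 22.5% and 5.12%, and MAGEL2 and DIRAS3 36.5% and 19.4% in EV with no KD peak. Among 47 MAGE, GAGE and SSX genes, which are testis-restricted cancer antigens, the counts were 4 and 2, with MAGEA4 at 53.0% and 9.72%, and 2 in each list with equal peak numbers. Histone genes had 13 of 87 members in EV and 7 in KD, a KD/EV ratio of 0.538 against 0.560 for all protein-coding genes, and H3C7, at 95.5% in EV, had no KD peak.

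NBPF, GOLGA and USP17L genes, families with many near-identical copies, had 17 of 68 members in EV and 12 in KD. Both counts exceeded those of all 10000 random lists, and the covered share was 4.43% and 1.49%. These values are uncertain because such copies share reads. With a fold enrichment of at least 3 the counts were 5 and 8.

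Olfactory receptor, keratin-associated and ribosomal protein genes met the 10% criterion less often than most length-matched random lists in both EV and KD. Olfactory receptor genes, the odorant receptors, had 4 of 387 members in EV and 2 in KD, below all matched random lists. Keratin-associated genes had 1 and 0 of 94, and ribosomal protein genes 1 and 0 of 77.

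Member counts of the germline, H3K9me3 machinery, interferon response, secreted factor, housekeeping, and kidney and neural lists lay between percentiles 30.1 and 86.4 of the random lists. Germline genes and genes of the H3K9me3 machinery had no member at 10% in either list, and 16 and 6 of 27, and 10 and 2 of 22, with any overlap. CBX5, which encodes the heterochromatin protein HP1 alpha, had 3.601% in EV and no KD peak. Interferon response genes had 1 of 25 members in EV and 0 in KD, with CGAS, the cytosolic DNA sensor, at 16.0% and 3.16%. Among 24 genes of secreted inflammatory factors the counts were 1 and 2: CCL5 had 29.9% and 15.3%, and CXCL1 no EV peak and 18.01%. Housekeeping genes, and kidney and neural genes, each had 1 member in either list, and housekeeping gene bodies were covered to 1.84% in EV and 1.11% in KD.

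**Figure D4:**
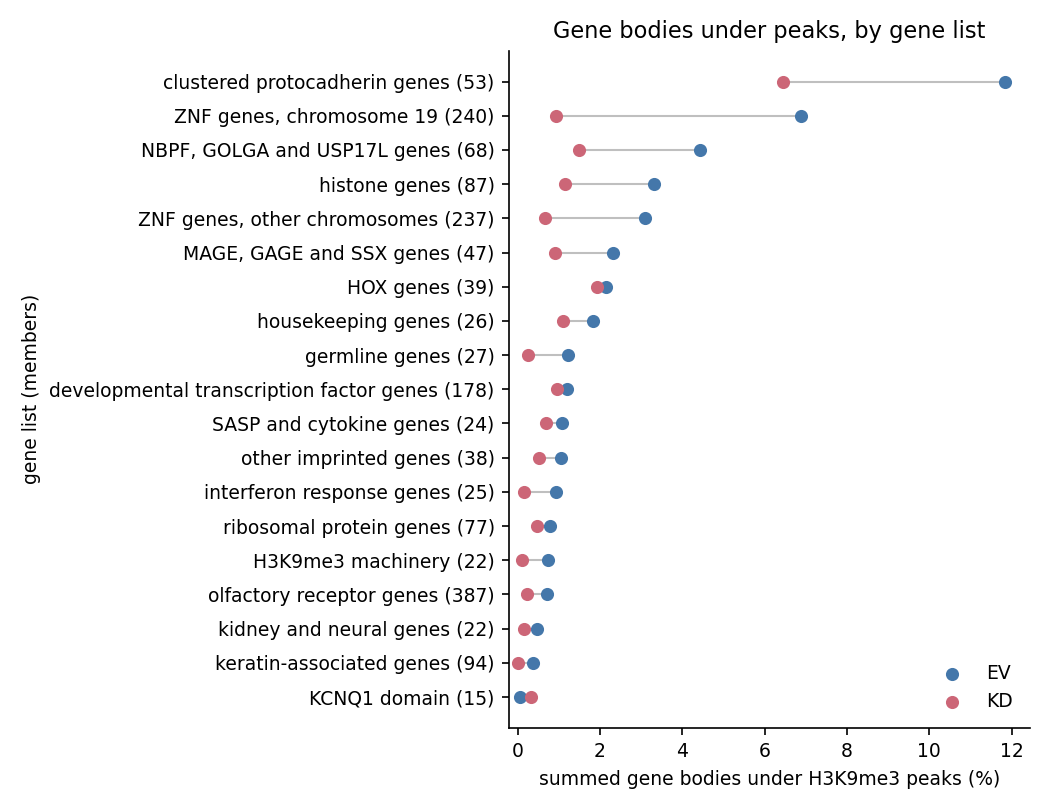
Percentage of summed gene bodies (overlapping bodies merged) under H3K9me3 peaks in EV and KD for each gene list, with the number of members in parentheses. Protocadherin and chromosome 19 ZNF genes have the highest EV values, 11.8% and 6.88%, and the KCNQ1 domain genes are the list with the higher value in KD.

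Among single protein-coding genes of at least 5 kb, covered share was higher in EV for 4413 and higher in KD for 507 of 16722, and the other 11802 had no peak in either list. The largest excess in EV was at ANHX, a homeobox gene, covered to 100% in EV and 24.9% in KD. TAFA5, which encodes a secreted brain protein, had 55.5% and 2.41%, from 44 EV peaks and 7 KD peaks. ERVFC1, an endogenous retrovirus envelope gene, had 76.8% and 36.2%. C17orf114 and MSANTD5 had 36.8% and 36.2% in EV and no KD peak. MAGEA4, ZNF268, ZNF605, ZNF878 and ZNF724 made up the rest of these 10.

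The largest excess in KD was at CT45A3, a cancer-testis antigen gene, with 24.5% and no EV peak. SLITRK5 (19.3%), PENK (17.5%), NPY (14.6%), TBXT (14.2%), HIC1 (12.4%) and NEFM (11.7%) also had a KD peak and no EV peak. PENK and NPY encode neuropeptide precursors, TBXT the mesoderm factor brachyury, and NEFM a neurofilament subunit. NKX3-2, a homeobox gene, had 9.14% in EV and 24.2% in KD, SCGB1C1 9.33% and 22.6%, and RBM15B 14.2% and 27.3%. The genes most covered in both lists were LOC124905153 (81.9% in EV and 79.8% in KD) and HRNR (59.2% and 54.4%), which encodes the skin protein hornerin. EPPK1, ISL2, SKOR1, DUX4, DAND5 and PCDH8 lay between 26.8% and 38.4% in both, and DMRTA2 had 45.9% and 30.3%. ERVFC1 belonged to this set too. DUX4 lies in a repeat array with near-identical copies, so its value is uncertain.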

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

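The tests of detection power, call strength and imprinted genes in this part were chosen after the results were seen, and those of a preference for CpG-island genes before theirs were.

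The following data lay outside the comparisons. A list without a genotype in its name held 15215 peaks on all sequences, 14362 of them on chromosomes. On sequences other than chromosomes, EV had 1699 peaks and KD 805.

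The KD list had fewer peaks and less covered length than EV. A lower detection power of the KD library could account for much of the lower peak number, since the EV peaks missing from KD were mostly weak ones. Of the 895 EV peaks with a −log10 p of at least 30, 99.9% were found in KD. Found means an overlap of at least 1 bp, so this does not address the covered length. Of the 1799 EV peaks of at least 5 kb, 90.9% were found, but only 49.1% of their bases lay under KD peaks. A difference in depth and a global decrease of H3K9me3 in KD both stay open, as these lists hold no reads by which to scale the libraries.

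Gene groups of like EV strength were recovered unequally in KD. Protocadherin genes had 77.6% of EV peaks found against 33.0% expected, chromosome 19 ZNF genes 18.1% (interval 14.2 to 22.6) against 24.6%, and ZNF genes on other chromosomes 27.1% (interval 21.1 to 33.8) against 29.0%, within the interval. A lower detection power alone is argued against by developmental transcription factor genes, a list made without the genes that prompted it, where 60.0% (interval 47.6 to 71.5) of 70 EV peaks were found against 29.5% expected. The same value is what a KD list that favours genes with CpG islands could give. No annotation of CpG islands was used, and developmental transcription factor genes only stand in for such genes. Another trait that they share cannot be told apart from a preference for CpG islands. Neighbouring peaks are not independent, so these intervals are too narrow. Whether such a preference comes from the library, its control or the knockdown was not tested, and the labels list no KD input.

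The KD-only peak at the 5′ end of KCNQ1OT1 is unlikely to be a call near the threshold, since its −log10 p of 11.2 stood at percentile 99.6 of the 1557 KD-only peaks, which are mostly weak, and at percentile 89.8 of all KD peaks, whose lowest value is 3.31. A list that favours CpG-island genes cannot be told apart. Protocadherin genes held 5 KD-only and 11 EV-only peaks, developmental transcription factor genes 20 and 28, and HOX genes 0 and 1. In protocadherin and developmental transcription factor genes the KD-only share of one-list peaks was thus above the 9.20% of all one-list peaks. The strongest of the 25 KD-only peaks in these groups reached 8.26 against 11.2. Only about 0.0963 peaks among 25 would reach 11.2 at the rate of all KD-only peaks. The bound set beforehand, that none of 20 or more such peaks reaching it would exclude this, was met but was therefore set wrongly. A gain at imprinted genes in general cannot be told apart either, with 13.6% (interval 2.91 to 34.9) of their 22 one-list peaks being KD-only against 9.20% of all one-list peaks; this share replaced a direct count, 3 KD-only against 19 EV-only, which list length alone would decide.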

How the results depend on the processing

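Every alternative here was planned except the one outside gene-free stretches and those on developmental transcription factor genes, which were chosen after the data were seen. Leaving out replicates was not possible with 1 library per group. No paired analysis was possible because each group has 1 library. The promoter setting and the repeat shares were not run, for lack of strand and sequence. Ratios are missing where a list had no member, as for ZNF, protocadherin and HOX genes at 50% of the gene body.

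The KD/EV ratio of covered length stayed below 1 in all settings, between 0.311 outside gene-free stretches and 0.560 with equal peak numbers. The ratio of peak number moved to 0.776 at a fold enrichment of at least 3 and is 1 by construction with equal peak numbers. The share of EV peaks overlapped by KD and that of KD peaks overlapped by EV were 39.7% and 88.4% at −log10 q of at least 2, 38.4% and 89.1% at 3, 46.2% and 72.9% at a fold of at least 3, 44.9% and 63.9% at 5, 35.0% and 86.3% after merging within 3 kb, 62.1% and 75.9% with equal peak numbers, 28.5% and 79.3% outside gene-free stretches, 24.99% and 84.7% with at least 50% of the peak covered, and 22.7% and 44.3% with reciprocal overlap. Shared bases over the union stayed within 1.5 times of 35.5%. On X the ratio of covered length was 0.720 with equal peak numbers, and all 23 chromosomes stayed lower in KD in the settings tried.

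The KD/EV ratio of members with a peak stayed below 1 for ZNF genes: 0.0862 on chromosome 19, with 0.405 at any overlap and 0.313 with equal peak numbers, and on other chromosomes 0.174, with 0.460 and 0.4. For protocadherin genes it went from 0.367 to 0.940 at any overlap and reversed to 1.80 at a fold of at least 3 and 1.22 with equal peak numbers. For developmental transcription factor genes it reversed from 0.853 to 1.5 at 50% of the gene body, 1.80 at a fold of at least 3 and 1.53 with equal peak numbers. For HOX genes it moved from 1 to 2 and 1.67 in the latter pair of settings. For NBPF, GOLGA and USP17L genes it reversed to 1.60 at a fold of at least 3. For other imprinted genes it moved from 0.2 to 0.8 at any overlap and 0.333 with equal peak numbers, for MAGE, GAGE and SSX genes from 0.5 to 1 with equal peak numbers, for olfactory receptor genes from 0.5 to 1 at a fold of at least 3, and for housekeeping genes from 1 to 0.6 at any overlap. The cause was not tested. Of the 18 planned lists, 11 had fewer and 1 had more members in KD as reported, against 7 fewer and 5 more both with equal peak numbers and at a fold of at least 3, 14 fewer and 2 more at any overlap, and 5 fewer and 1 more at 50% of the gene body. The fold cut of 3 keeps 11365 of 12650 KD peaks and 14645 of 24665 EV peaks, so ratios under it depend on the scaling of the folds, which is not known. Depth is unknown, so the limit it sets on weak peaks cannot be given.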

Other observations

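The developmental transcription factor genes were listed after the named genes were seen, and all values in this part were chosen after the data were examined, except the count and extent of the list without a genotype.

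Developmental transcription factor genes, such as members of the PAX, SOX, FOX and LHX families, carried the mark more often than length-matched genes in both lists. Of 178 genes, 34 met the 10% criterion in EV and 29 in KD, each above all 10000 random lists, whose medians were 8 and 6. The direction between the lists turned with the setting: 19 in EV and 29 in KD with equal peak numbers, 15 and 27 at a fold enrichment of at least 3, and 8 and 12 at 50% of the gene body. Their covered share was 1.201% in EV and 0.956% in KD. The genes that had prompted the list were left out of it.

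The strongest KD-only peaks lay in the non-coding genes LINC01191 and LINC02992 and outside genes on chromosome 5, both with a −log10 p of 16.1, and another outside genes on chromosome 17 had 12.1. The one on chromosome 17 lay in a gene-free stretch, where values are uncertain. In protein-coding genes, those among the 10 strongest other than the one at KCNQ1OT1 lay in TENM3 (fold enrichment 7.36, −log10 p 12.5), GRK1 (6.15 and 11.3), CDKN2A (6.34 and 11.03) and ELAVL2 (5.90 and 10.3). CDKN2A encodes the cell cycle inhibitor p16, and its peak lay at chromosome 9, 21970814 to 21971303. The strongest EV-only peak, with a −log10 p of 43.6 and a fold enrichment of 2.45, lay outside genes on chromosome 1. It too lay in a gene-free stretch, so it is uncertain. Those of the 10 strongest EV-only peaks in protein-coding genes lay in SLC14A2, with a −log10 p of 23.6, and PTPRN2, with 23.5.

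The list without a genotype covered 29.8 Mb of the chromosomes, 74.9% of it in gene-free stretches. Of its peaks, 50.2% (interval 49.4 to 51.0) were overlapped by EV and 35.6% (interval 34.8 to 36.4) by KD. It overlapped 588 of the 895 EV peaks with a −log10 p of at least 30 and 256 of the 301 such KD peaks. It covered 3.37% of chromosome 19 ZNF gene bodies and 1.00% of protocadherin gene bodies. In the KCNQ1 domain it had 2 peaks, at 2633639 to 2634649 and 2637875 to 2638848, and none at the 5′ end of KCNQ1OT1.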
